A study of Homo sapiens with 12 samples.

How the data were processed

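RNA immunoprecipitation followed by sequencing was measured in 12 libraries from HK2, an established human kidney epithelial cell line. Per the labels' protocols, all cells were transfected with 10 µg of a plasmid encoding FLAG-tagged human Arid5a and kept for 3 h with IL-17 at 200 ng/mL or with medium alone. Lysates were precipitated with an antibody against FLAG or with mouse IgG1, the background control. Per the labels' protocols, beads were treated with DNase I and a protease, RNA was taken up in acid phenol or TRIzol, and libraries were made with a low-input full-length cDNA kit. The labels do not say which library had which extraction. Groups and replicate numbers came from the sample titles, giving 4 groups of 3 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

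The deposited estimated counts hold 60708 features per library, with versioned Ensembl identifiers. Per the submitters' processing notes, STAR 2.7.9, RSEM 1.3.1, DESeq2 1.36.0, R 4.2.0 and the builds GRCh38 and hg38 were used; their roles are not given in the sources used here. The deposited table named for FPKM holds TPM values, since each column sums to 1000000, and it was treated as TPM. A mismatch with the planned FPKM unit therefore changed only the name of the log-scale alternatives. Of the counts above 0, 18.0% were not whole at a tolerance of 0, and all were rounded to whole numbers before testing. Of the features, 12344 were 0 in every library.

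The files do not pair identifiers with gene names. The reference table held no Ensembl identifiers, so 0 of the 60708 identifiers matched it. The 15 gene lists fixed before the data were examined, with 446 entries, were therefore not tested. No feature was assigned to the transfected gene, so its level, which plasmid-derived counts could raise, is not identified among the values given. The rule for named features took, per comparison, those with the largest log2 fold changes in each direction. It required an adjusted p under 0.05, a mean of at least 5 CPM (counts scaled to library size) in the higher group and no overlap between the libraries of both groups. Because names were lacking, at most 2 identifiers per direction are given. Features that share reads with near-identical copies are uncertain, because estimated counts divide such reads. Among 21794 features with a total of 100 or more, 82 fell in 33 sets with identical rounded counts in all libraries. Whether counting used strand is not given in the sources used here.

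Total estimated counts ranged from 746911 to 17723100. A count of 0 allows up to 4.02 CPM in the shallowest library and 0.169 CPM in the deepest, from a floor of 3 counts, which covers counting error only. Folds against a group at 0 were computed against 3 counts over the summed total of that group, without composition factors. Where the lower group of a named feature held 1 to 3 counts, the ratio of pooled counts is given with an exact conditional binomial interval.

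The 6 comparisons shared 1 model of all 12 libraries. Counts were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. This left 24040 features; Benjamini-Hochberg adjusted p under 0.05 made a call. The common dispersion was 0.953, estimated over all 12 libraries. Standard errors of a comparison therefore do not measure the spread of its own libraries alone. The procedure was tested on simulated data with 24040 features, in which it recovered 45% of 16-fold and 3% of 4-fold changes for the enrichment in medium. For the enrichment in IL-17 these shares were 58% and 11%. They were 51% and 9% for the IL-17 effect in IgG, and 47% and 9% for that in FLAG. Unchanged features called numbered 4 for the enrichment in medium and 9 for that in IL-17. For the IL-17 effects these false calls numbered 6 in IgG and 5 in FLAG. The simulated libraries shared a common mean profile, without outlying libraries or sets of identical features, so recovery in the real data may differ.

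Alternatives fixed before the data were examined were RLE factors, library size only, upper-quartile scaling, no filter and a filter of 50 counts in 3 libraries. Others were DESeq2 1.42.0, fits of only the compared groups, a replicate block, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library for the counts of calls. Alternatives chosen after seeing the data were robust fitting, edgeR's adjusted deviances, leaving out libraries that stood apart, leaving out the 10 most abundant features, and thinning to 740000 counts. Keeping identical features once and leaving out the shortest 10% of features were also chosen after seeing the data, as was leaving out each library for the correlations of fold changes.

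Apparent effective length was the ratio of estimated count to TPM (at least 20 counts and 0.2 TPM), scaled within each library and divided by the median of tested features. It existed for 23132 tested features. Similarity of libraries was measured on log2 CPM with a prior count of 2.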

Results

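RNA bound by FLAG-tagged Arid5a was compared with RNA recovered by control IgG in HK2 cells, with and without IL-17, an inflammatory cytokine. Each of the 4 groups had 3 libraries. Total estimated counts averaged 3556170 ± 2694230 (SD, n = 3) in IgG medium and 10513200 ± 5238420 (SD, n = 3) in IgG IL-17. They averaged 5427200 ± 2692820 (SD, n = 3) in FLAG medium and 16342800 ± 2329350 (SD, n = 3) in FLAG IL-17. Over both antibodies, IL-17 libraries were deeper than medium libraries by 8936280 counts on average (n = 6 each, exact two-sided permutation p = 0.00866, 0.026 after Benjamini-Hochberg adjustment over 3 measures). Depth and treatment were therefore not independent in these libraries. The permutation treated the FLAG and IgG libraries of a treatment as independent units, which the labels do not state. The labels give no batch, so whether preparation or sequencing coincided with treatment is not known, and this limit holds for every IL-17 effect given.

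Replicates differed in how alike they were. Pearson correlations of log2 CPM across features ran from 0.96 to 0.968 within FLAG IL-17 and from 0.854 to 0.886 within IgG IL-17. Within FLAG medium they ran from 0.552 to 0.78, and within IgG medium from 0.553 to 0.693. FLAG IL-17 and IgG IL-17 libraries correlated at 0.84 to 0.934, so these antibodies' libraries were more alike than the replicates of either medium group. The medium libraries were also shallower on average, and correlations at equal depth were not computed. How much depth contributed is therefore not known. Features are not independent replicates.

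Library content also varied within groups. At an equal depth of 740000 counts, IgG IL-17 replicate 1 held 32434 features, IgG medium replicate 2 held 25746 and FLAG medium replicate 1 held 25327. The other 9 libraries held between 10600 and 21452. The feature ENSG00000196843.17, singled out after its values were seen, took 8.93%, 16.2% and 11.9% of counts in those 3 libraries. Its highest share elsewhere was 2.48%. The files do not say which gene this feature is. That it is the transfected gene is not excluded, in which case its share could include plasmid-derived counts. These 3 libraries and IgG medium replicate 1, the shallowest, are the 4 libraries that stood apart.

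**Figure D1:**
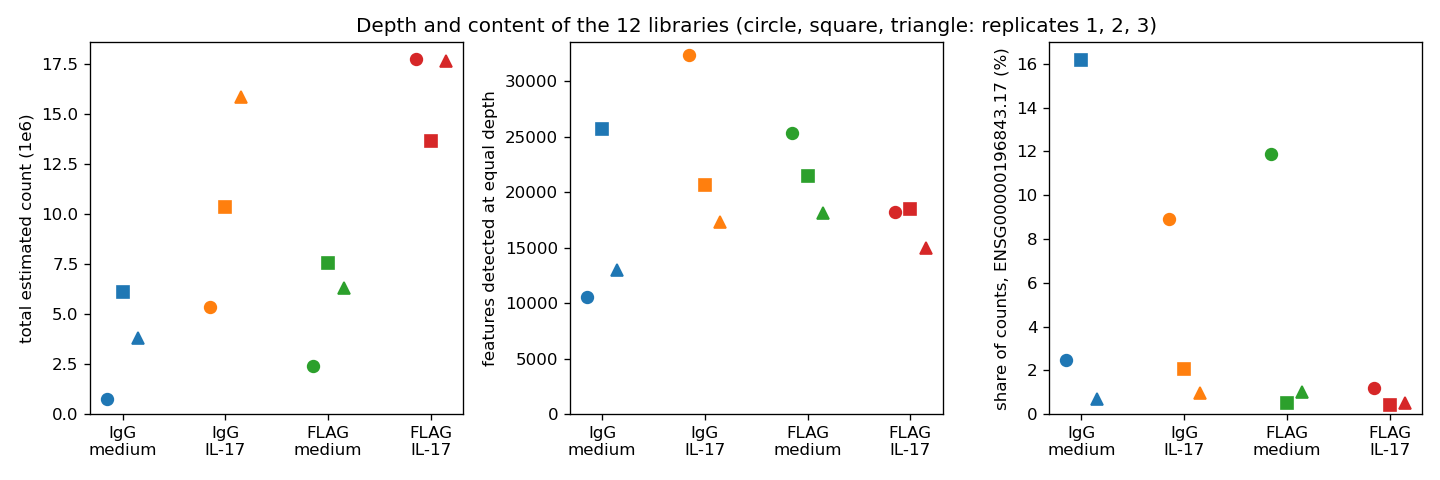
Each point is 1 library, grouped by antibody and treatment on the horizontal axes. The vertical axes give total estimated count in units of 1e6, features detected at 740000 counts, and the percentage of counts of ENSG00000196843.17, which reached 16.2% in IgG medium replicate 2.

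The first question was which transcripts FLAG precipitation enriched over IgG in medium. No feature met the threshold: edgeR called 0 of 24040 higher and 0 lower, with a smallest adjusted p of 0.322. At an unadjusted p under 0.05, 1002 features were higher and 576 lower in FLAG by edgeR, against 1202 expected in all. This balance was not stable: it was 901 higher and 1001 lower with upper-quartile scaling, 960 and 1086 without FLAG medium replicate 1, 999 and 1305 without IgG medium replicate 3, and 4180 and 868 without IgG medium replicate 2. DESeq2 called 93 higher and 47 lower, and limma called 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1). FLAG and IgG libraries did not overlap for 6.19% of features, where chance gives 10% if no values tie. Ties at 0 lower that chance share: IgG medium replicate 1 had counts for only 9948 of the 24040 tested features. The 6.19% can therefore not be read as below chance. The median standard error of a log2 fold change was 1.38, so a typical 95% interval reached 2.84 to either side. By edgeR, leaving out IgG medium replicate 2 gave 9 higher features, leaving out IgG IL-17 replicate 1 or FLAG medium replicate 2 gave 1 higher, and leaving out IgG medium replicate 3 gave 1 lower. Leaving out the 4 libraries that stood apart gave 981 higher and 256 lower, but this set FLAG medium against a single IgG medium library, assumed to vary like the others.

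The same comparison with IL-17 also gave 0 higher and 0 lower features by edgeR, with a smallest adjusted p of 0.923. At an unadjusted p under 0.05, edgeR found 136 higher and 540 lower, against 1202 expected in all. DESeq2 called 1 higher and 8 lower, and limma called 1 on log2(TPM + 1) and 0 on log2(TPM + 0.1). Fitted on the 6 IL-17 libraries alone, edgeR also called 0 in either direction, but 2100 features were higher and 2248 lower at an unadjusted p under 0.05. Libraries did not overlap for 26.9% of features, against 10% by chance if no values tie and less with ties. The median standard error was 1.34, giving a typical 95% interval of 2.76 to either side. The dispersion behind it was shared by all 12 libraries, including the less alike medium replicates. This interval therefore does not measure the spread of the IL-17 libraries alone. Leaving out IgG IL-17 replicate 3 gave 2 higher features. Without the 4 libraries that stood apart, 1582 were higher and 739 lower at an unadjusted p under 0.05.

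Averaged over both treatments, edgeR called 0 features in either direction, with 427 higher and 568 lower at an unadjusted p under 0.05, a balance that turned to 1893 higher and 558 lower without IgG medium replicate 2. DESeq2 called 13 higher and 20 lower for this mean, and limma called 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1). The test of a change of enrichment with IL-17 likewise gave 0 in either direction by edgeR, with a smallest adjusted p of 0.373. For this change, 258 features were higher and 1509 lower at an unadjusted p under 0.05, DESeq2 called 12 higher and 96 lower, and limma called 0 with either pseudocount. Its median standard error was 1.91 on the log2 scale. Leaving out IgG medium replicate 2 gave 2 higher features for the mean, and 1 higher and 2 lower for the change. The mean also had 1 higher feature without IgG IL-17 replicate 3 or FLAG medium replicate 2. Without the 4 libraries that stood apart, the mean gave 902 higher and 126 lower and the change gave 111 and 556, again with a single IgG medium library.

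Enrichment in medium and in IL-17, which share no library, correlated at Pearson r = -0.155 and Spearman rho = -0.169 across 24040 features. The sign matched for 44% of features. At an unadjusted p under 0.05, 5 features were higher in both, where independent lists give 5.67, and 14 were lower in both, where they give 12.9. A further 42 had opposite directions. The correlation was -0.47 without IgG medium replicate 2 and 0.153 without FLAG medium replicate 1.

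**Figure D2:**
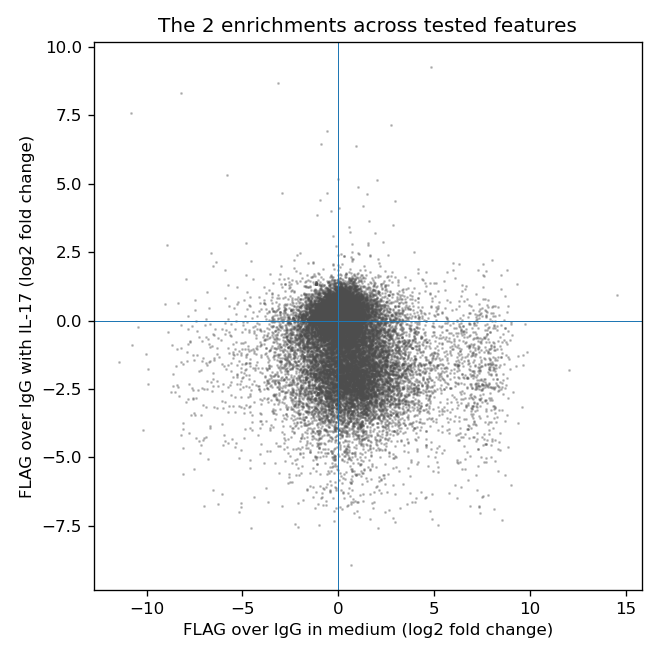
Each point is 1 of 24040 tested features. The horizontal axis is the log2 fold change of FLAG over IgG in medium and the vertical axis that with IL-17; the points show no shared direction, with Pearson r = -0.155.

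The next question was how IL-17 changed RNA recovered with each antibody. In IgG libraries, edgeR called 3 features higher and 0 lower. ENSG00000277209.1 had a mean of 619 ± 382 CPM (SD, n = 3) with IL-17 and a count of 0 in every IgG medium library. That made it at least 2013-fold higher, with an edgeR adjusted p of 1.37e-06. Its estimated counts with IL-17 were not whole, such as 2267.21 in IgG IL-17 replicate 1, so some reads were divided with other features. ENSG00000207389.1 had 1335 ± 1223 CPM (SD, n = 3) against a rounded count of 0 in IgG medium, at least 4396-fold higher, with an edgeR adjusted p of 0.0208. It was not absent without IL-17: FLAG medium replicates 1, 2 and 3 had 8.04, 2.48 and 1054.5 CPM of ENSG00000207389.1. Its estimated counts were not whole, such as 28.78 in FLAG medium replicate 1, so some reads were divided with other features. How much of its fold reflects that division was not tested. At an unadjusted p under 0.05, edgeR found 912 features higher and 427 lower. This balance turned to 750 and 864 with upper-quartile scaling, and to 78 and 895 by limma on log2(TPM + 1). DESeq2 called 122 higher and 196 lower. For lower features, limma called 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1). RLE factors gave 3 higher and 6 lower and upper-quartile scaling 2 and 2. Leaving out IgG medium replicate 1 gave 64 higher and 11 lower. Higher features numbered 8 without IgG IL-17 replicate 1 or IgG medium replicate 2, and 10 without FLAG medium replicate 1. They numbered 5, 5 and 6 without FLAG IL-17 replicates 1, 2 and 3. ENSG00000207389.1 lost its call without IgG IL-17 replicate 2, IgG medium replicate 2 or IgG medium replicate 3, with edgeR adjusted p of 0.0791, 0.11 and 0.149, and its adjusted p reached 0.815 over the alternatives.

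In FLAG libraries, edgeR called 53 features higher with IL-17 and 1 lower. At an unadjusted p under 0.05, 734 were higher and 1889 lower, but these numbers were 1420 and 1691 with a replicate block and 2929 and 2491 without the 4 libraries that stood apart. The median log2 fold change of all tested features was -0.29, and it was -0.05 without FLAG medium replicate 1 and -1.06 without FLAG IL-17 replicate 2. ENSG00000277209.1 had a mean of 969 ± 78.8 CPM (SD, n = 3) with IL-17 and a count of 0 in each FLAG medium library. It was at least 4342-fold higher, with an edgeR adjusted p of 1.77e-07. Its estimated counts were not whole here either, such as 17556.1 in FLAG IL-17 replicate 1. ENSG00000206652.1 had 16405 rounded counts with IL-17 and 1 in medium, over 3 libraries each, with an edgeR adjusted p of 0.0212. The ratio scaled to library totals was 5448, with an exact 95% interval of 978 to 215192 that covers counting error only, and its level with IL-17 ran from 0.185 to 1276 CPM between libraries. Estimated counts of ENSG00000206652.1 were not whole, such as 1742.9 in FLAG IL-17 replicate 1, so some reads were divided with other features. The part of this division in the ratio was not tested. ENSG00000259605.3, the feature that was lower, had 9.29 ± 6.64 CPM (SD, n = 3) in medium and 0.0983 ± 0.0929 CPM (SD, n = 3) with IL-17. Its log2 fold change was -6.37 ± 1.24 (SE, edgeR adjusted p = 0.0212). ENSG00000206652.1 lost its call without IgG IL-17 replicate 2 or 3, FLAG IL-17 replicate 2, IgG medium replicate 2 or any 1 FLAG medium library. ENSG00000259605.3 lost its call without any 1 FLAG IL-17 library and without FLAG medium replicate 2 or 3. For both, the adjusted p reached 0.51 over the alternatives, in limma on log2(TPM + 0.1).

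The 53 higher features were short. Of these, 52 had an apparent effective length, with a median of 0.00984 of that of tested features, and 51 lay in the shortest 10%. None of 10000 random lists of the same size, matched on mean level, had so short a median. The lists drew features separately, whereas the 53 include sets of features with shared counts, so this overstates how unusual the median is. The 53 features made up 36 distinct count profiles, because several features had identical counts in all libraries, up to 12 in a set. Some of these profiles differed in a single library, so the 36 are not independent either. The median CPM of the 53 features was 254 in FLAG IL-17 and 14.8 in FLAG medium. In IgG libraries it was 140 with IL-17 and 21.1 in medium. All 53 had a higher fitted level with IL-17 in IgG libraries too, but 2 were called there. Their median CPM was 48.8 in IgG medium replicate 1, against 10.4 and 6.15 in replicates 2 and 3, which lowers the IgG fold.

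This count moved with the libraries used. It was 2 without the 3 libraries that held the most features at equal depth, 5 without FLAG medium replicate 3, 6 without FLAG medium replicate 2, 11 without FLAG medium replicate 1, 7 without FLAG IL-17 replicate 2 and 82 without IgG medium replicate 1. It was 21 without FLAG IL-17 replicate 3 and 24 without IgG IL-17 replicate 2 or 3. Lower features numbered from 0 to 26, the latter without IgG medium replicate 3. RLE factors gave 4 higher and 1 lower, and DESeq2 called 160 higher and 869 lower. ENSG00000277209.1 was called in both antibodies' libraries under all 17 alternatives that kept it and in all 12 fits that left out a library. All these fits used the same division of its reads between features, so they do not test that division.

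**Figure D3:**
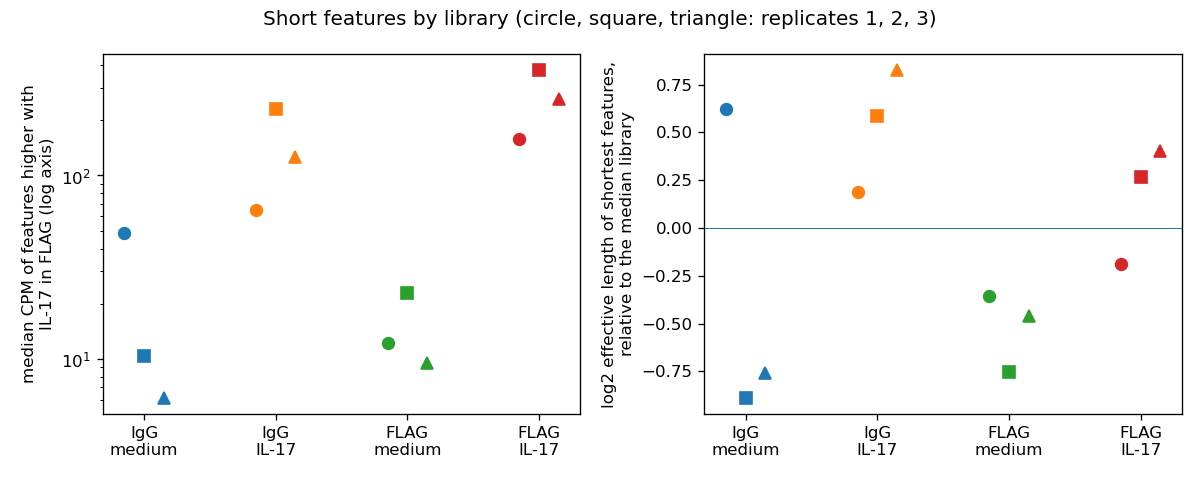
Each point is 1 library. The vertical axes give the median CPM of the 53 features on a log axis and the log2 apparent effective length of the 129 shortest well-measured features relative to the median library; IgG medium replicate 1 had 48.8 CPM and 0.62, against 10.4 and 6.15 CPM in the other IgG medium libraries.

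The IL-17 effects in IgG and in FLAG, which share no library, correlated at Pearson r = 0.0464 and Spearman rho = 0.119 across 24040 features, a comparison chosen after seeing the data. At an unadjusted p under 0.05, 151 features were higher in both, where independent lists give 27.8, and 58 were lower in both, where they give 33.6. Another 38 had opposite directions. The Pearson correlation was -0.388 without IgG medium replicate 2 and 0.286 without IgG IL-17 replicate 1.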

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

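The robust, adjusted-deviance, left-out set, abundance, thinning, identical-feature and short-feature alternatives, all settings of the correlation of both IL-17 effects, and leaving out single libraries for the correlation of both enrichments, were chosen after seeing the data. Counts are given as higher and lower features by edgeR unless a tool is named; the cause of each move was not tested, except where features or libraries were removed. ENSG00000277209.1 was called in both IL-17 effects in all 12 fits that left out a library and under all 17 alternatives that kept it, with adjusted p up to 0.00488. These fits shared the same division of its reads between features, which was not tested. No named feature changed sign. Leaving out the 4 libraries that stood apart leaves 1 IgG medium library, assumed to vary like the others, so its counts for all comparisons with IgG medium rest on that library. A count of 0 allows up to 4.02 CPM in the shallowest library, so lower levels were not detectable there. Leaving out the transfected gene and the gene list tests were not run, because identifiers were not paired with names.

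For the enrichment in medium (0 and 0), no filter gave 9 and 39, DESeq2 93 and 47, limma on log2(TPM + 0.1) 1 higher, and leaving out the 4 libraries that stood apart 981 and 256. For the enrichment in IL-17 (0 and 0), no filter gave 2 and 2, DESeq2 1 and 8, limma on log2(TPM + 1) 1 higher, and leaving out those 4 libraries 3 and 2. For the mean (0 and 0), no filter gave 5 and 36, DESeq2 13 and 20, limma on log2(TPM + 0.1) 1 higher, and leaving out those 4 libraries 902 and 126. For the change (0 and 0), no filter gave 8 and 7, DESeq2 12 and 96, and leaving out those 4 libraries 111 and 556.

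For the IL-17 effect in IgG (3 and 0), library size only gave 5 higher, RLE factors 6 lower, upper quartile 2 lower, the strict filter 6 lower, no filter 43 and 26, DESeq2 122 and 196, and limma on log2(TPM + 0.1) 1 lower. Robust fitting gave 2 lower, adjusted deviances 20 and 10, leaving out the abundant features 5 lower, thinning 10 lower, leaving out the shortest 10% 0 higher (662 at an unadjusted p under 0.05 by edgeR; DESeq2 and limma were not run on that set) and leaving out the 4 libraries 1191 and 440. For that in FLAG (53 and 1), RLE factors gave 4 higher, upper quartile 7 and 0, the strict filter 4 higher, no filter 137 and 91, DESeq2 160 and 869, limma 5 higher with either pseudocount, and only the groups compared 8 lower. Robust fitting gave 28 higher, adjusted deviances 116 and 372, leaving out the abundant features 21 and 4, thinning 3 higher, identical features kept once 34 higher, leaving out the shortest 10% 0 and 0 (324 and 2517 at an unadjusted p under 0.05 by edgeR). Leaving out the 3 libraries with the most features gave 2 and 0, and leaving out the 4 libraries 464 and 188.

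Whether replicate numbers pair the libraries stays open, since the labels do not say and the data do not settle it. Of 18 same-numbered pairs, 9 had correlated deviations above 0.1, with a range of -0.14 to 0.468, and 10 correlated best with their own number. For number 3 alone, all 6 pairs were above 0.1 (0.213 to 0.392) and best with their own number, a hint from the data and not the design. With a replicate block, edgeR gave 1 and 3 for the enrichment in medium, 1 higher for the mean, 2 and 1 for the change, 25 and 8 for the IL-17 effect in IgG, and 99 and 37 for that in FLAG.

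Leaving out single libraries gave, for the enrichment in medium, 0 to 9 higher and 0 to 1 lower, and for that in IL-17 0 to 2 higher. It gave 0 to 2 higher for the mean, and 0 to 1 higher and 0 to 2 lower for the change. For the IL-17 effect in IgG it gave 2 to 64 higher and 0 to 11 lower, and for that in FLAG 5 to 82 higher and 0 to 26 lower, the 26 without IgG medium replicate 3. The correlation of both enrichments ran from -0.47 to 0.153 and that of both IL-17 effects from -0.388 to 0.286; the latter was 0.24 with the strict filter. Relative to the median log2 fold change of -0.29 in FLAG with TMM, RLE factors moved the median of all features to -0.89, library size only to -0.92 and upper quartile to -0.62, while it was -0.07 after thinning, -0.05 with the replicate block, -0.04 with the strict filter, -0.03 with only the groups compared and 0 with no filter, and -1.06 to -0.05 when single libraries were left out.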

Other observations

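The tests on the 3 libraries with the most features and both fragment-length tests were chosen after their results had been seen in part; the DESeq2 and regrouping tests were set out before. The thinning test was set out before its fold changes were seen, but after the number of calls in thinned libraries was known.

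ENSG00000277209.1 was the only feature with a rounded count of 0 in all 6 medium libraries, among 26950100 counts, and over 5 CPM in all 6 IL-17 libraries. There were 0 features with the opposite pattern. No test of its cause was run.

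In the first pattern, IgG IL-17 replicate 1, IgG medium replicate 2 and FLAG medium replicate 1 held the most features at equal depth, by at least 3875 over any other library. At full depth this order did not hold, so thinning defines the pattern and is no separate test of depth. DNA carry-over, genomic or from the plasmid, is a candidate explanation that stays open. Length and pooled CPM in these 3 libraries correlated at Spearman rho = 0.478 across 11165 features under 1 CPM in the other 9, where the trend was also present at 0.306, but the features were picked for being scarce there and RNA counts also rise with length, so this decides nothing. The design gives no biological explanation to test, since the 3 libraries come from 3 groups.

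In the second pattern, 53 features were higher and 1 lower with IL-17 in FLAG libraries, and after thinning to equal depth 3 of the 53 were still called by edgeR, with a median adjusted p of 0.15, while all 53 kept an unadjusted p under 0.05; why the calls ended was not tested. Their median log2 fold change was 3.68 (median SE 0.89) against 4.18 (median SE 0.85) before. Random thinning leaves expected ratios of CPM unchanged, so this does not decide whether depth contributed to the fold. Fragment length is a candidate explanation that stays open: the shortest features had effective lengths 0.78 log2 units higher in IL-17 than in medium libraries (exact two-sided permutation p = 0.0238, n = 6 each, adjusted 0.0357), and the 241 features as short as most called ones had a median log2 fold change of 2.22, or 1.93 without the 43 called among them. The third measure tested, the share of counts in the shortest 10% of features, was 27.2 ± 5.87% (SD, n = 6) with IL-17. In medium it was 20.6 ± 8.51% (SD, n = 6; exact two-sided permutation p = 0.147, adjusted 0.147). These permutations treated FLAG and IgG libraries as independent units, which the labels do not state. The whole shortest 10% had a median of 0.03 in FLAG. That set reaches a relative length of 0.383, against 0.0209 for the 241 features, so its median decides nothing about them. Those 241 features had a median of 0.82 in IgG libraries, where mean effective lengths were 0.53 with IL-17 and -0.34 in medium. In FLAG the mean effective lengths were 0.16 and -0.52. The IgG value decides nothing, because effective lengths in IgG medium replicates 1, 2 and 3 were 0.62, -0.89 and -0.76. IgG medium replicate 1, without IL-17 but with effective lengths like those of IL-17 libraries, held the 53 features at a median of 2.59 log2 units above the other IgG medium libraries with TMM and 1.61 by library size only, but 1 library cannot settle this, and an effect of IL-17 on short RNAs and a preparation or sequencing batch that coincided with treatment stay open.

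In the third pattern, DESeq2 called 140 features for the enrichment in medium, 93 higher and 47 lower, where edgeR called 0 (1578 at an unadjusted p under 0.05; limma called 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1)). The shallowest library as the cause is argued against for 102 of the 140, which DESeq2 still called without IgG medium replicate 1. The total of 209 calls without it decides nothing, because leaving out any compared library raised the number. Leaving out any of the other 5 libraries gave at least 175 calls, with 79 to 132 of the 140 among them, so no single library accounts for all of the calls. Direction and number still moved with single libraries, to 76 higher and 184 lower without FLAG medium replicate 1 and to 2560 higher and 406 lower without IgG medium replicate 2. What separates the tools here stays open, and FLAG binding was not tested apart from it.

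Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. The real count was 54 for the IL-17 effect in FLAG, with a highest other split of 0, and 3 for that in IgG, with a highest other of 6; 1 and 2 of the splits, respectively, called as many as the real one. For the other comparisons the real count was 0 by edgeR, with the unadjusted and other tools' counts given for each above, so every split calls as many by construction (10 of 10 for both enrichments, 40 of 40 drawn for the mean and the change) and nothing follows about chance. The highest other splits called 5 features for the enrichment in medium, 0 for that in IL-17, 1 for the mean and 286 for the change. For the change, 16 of the 39 other splits called features; this may point to a structure of the libraries beyond the groups, which was not tested.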
